A study of Homo sapiens with 8 samples.

How the data were processed

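Expression was measured on 8 Affymetrix human arrays with biotin-labelled total RNA, 1 array per lymph node sample, from 4 vehicle-treated and 4 doxycycline-treated mice. The labels call the samples biological replicas. The deposited values are log2 expression values, 1 per probe set and array, made with RMA (background correction, normalization between arrays and summary of the probes) per the submitters' processing notes. The RMA version, the image analysis and the genome build are not given in the sources used here, so no coordinates are printed. The log2 scale follows from RMA and from the range of the values, and the values were used without gene-wise centring. Scanner files were not used here, so signal over background per probe was not assessed. RMA forces similar distributions on all arrays, so a change in the total amount of human RNA in a sample would appear as changes of single genes relative to the rest.

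The table held 18565 probe sets. The platform annotation gave 1 gene symbol for 17509 probe sets, several for 0 and none for 1056, which stayed unnamed here and entered no main test. All 17509 gene identifiers matched the RefSeq genes used for names. For the 16 genes with more than 1 probe set the one with the highest mean was taken, and for 5 of these genes the probe sets differed in sign. This left 17491 genes. How far the human probes also detect mouse transcripts was not measured, so a value can hold signal of both species.

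Groups were taken from the sample labels. Differences are doxycycline minus vehicle on the log2 scale, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The tests, the 41 gene lists (1156 distinct genes, 1030 measured) and the alternatives were set before the data were examined, except where the closing section says otherwise. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members were also adjusted over the list alone, without correction for the 41 lists, so some such calls can arise by chance. Means of the 9 host marker lists were compared with an exact two-sided permutation test over the 70 assignments of 8 arrays to 4 and 4, which can give no p below 0.0286. Data tables were handled in R with the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

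Named genes followed a rule set before the data were examined. They are MYC, MAX and any MYC network gene past the threshold, up to 12 genes per direction past the threshold with groups that do not overlap, filled to 6 per direction with the smallest p where fewer passed, and for each described list up to 3 members with the smallest p in the list's direction and 1 the other way. DCBLD2, TGFBI, ERRFI1, GAPDH, ACTB, MLANA and further genes given only for vehicle replicate 1 or for skeletal muscle were chosen after their values were seen.

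The fits were tested on simulated data with the means and spread of these arrays. Of 100 genes changed by 1 log2 unit 81% were called in the right direction, of 100 changed by 2 log2 units 100%, and 11 of 17291 unchanged genes were called. Of 10 lists shifted by 0.3 log2 units 10 were called, and of 30 unshifted lists 0. The simulated errors were independent between genes, which the real ones were not in every list. The correlation estimated from these arrays was 0.76 for ribosomal proteins and 0.29 for G2 and mitosis, but near 0 for other lists such as MAPK output. The simulated lists therefore do not give the rate of false list calls here, where other splits of the arrays called 5 to 16 lists.

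Alternatives were the replicate number as a block, centring of array medians, quantile and cyclic loess normalization, removal of the dimmest 25% or 50% of genes, the mean of a gene's probe sets, another variance model, array weights, each array left out, all probe sets, an adjusted p threshold of 0.1, a fold threshold of 1.5 and the unmoderated statistic. For lists they also included an estimated correlation, fry and camera on ranks. For the host marker means they included a fit with only members above the median level. The number of arrays limits the precision.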

Results

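The data were 8 one-colour Affymetrix human gene expression arrays, 4 from vehicle-treated and 4 from doxycycline-treated BALB/c nude mice. The mice, an athymic strain, carried subcutaneous tumours of SkMel147, a human skin melanoma cell line. Doxycycline in the drinking water served to switch on Omomyc in the tumour cells. Omomyc is a dominant-negative protein built from the dimerization domain of the transcription factor MYC, and it keeps MYC from its target genes. Treatment began at a tumour volume of about 750 mm3, and metastatic lymph nodes were collected 2 days after treatment. The sample labels name lymph node metastases as the tissue, whereas the series' design text speaks of melanomas. Whole nodes were homogenized, so mouse host RNA and human tumour RNA entered the same hybridization. Each array gave a log2 value for 18565 probe sets, of which those with a gene symbol stood for 17491 genes. The array medians lay between 5.07 and 5.12. With 4 arrays per group, the number of arrays limits the precision: the median standard error of a gene's difference was 0.15 on the log2 scale.

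One array stood apart from the rest before any comparison. Vehicle replicate 1 had a mean correlation of 0.941 with the other 7 arrays across genes, which are not independent replicates, and its single correlations lay between 0.930 and 0.951. The other 7 arrays correlated with each other at 0.972 to 0.983, whichever group they came from. The first principal component held 40.6% of the variance and placed vehicle replicate 1 at 52.9, against values from -15.6 to 1.07 for the other 7 arrays. The genes with the largest excess in this array over the mean of the other 7 included RPS24, a ribosomal protein gene, at 10.17 against 4.89. They also included DCBLD2, a membrane receptor, at 9.81 against 5.01, TGFBI, a secreted matrix protein, at 8.78 against 4.74, and NT5E, which encodes the ecto-enzyme CD73, at 9.15 against 5.28. GAPDH, a glycolytic enzyme gene, was at 9.40 in vehicle replicate 1, which was 3.05 above the mean of the other 7 arrays. ACTB, which encodes beta-actin, lay between 7.69 and 8.37 in all 8 arrays, with both ends of that range outside vehicle replicate 1.

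The comparison of doxycycline with vehicle asks how gene expression in the metastatic nodes differed 2 days after treatment. Whether Omomyc was expressed in these nodes was not checked here. The share of human tumour RNA per array was not measured, so a response of the tumour cells can be missed. RPL6, TXN and MCL1, picked for their excess in vehicle replicate 1, averaged 4.28, 4.11 and 3.57 in the other 7 arrays. Those means lay below the array medians, whereas ACTB lay above them in every array. Among markers of adipocytes, a host cell type, FABP4, CIDEC and LPL were higher with doxycycline by 0.58 ± 0.13 (SE), 0.62 ± 0.18 (SE) and 0.67 ± 0.20 (SE) on the log2 scale when adjusted over the list alone. With each of the 8 arrays left out in turn, the FABP4 call was lost in 0 fits, the CIDEC call in 2 and the LPL call in 3, and the adipocyte list had an adjusted p of 0.387 with an estimated correlation. FABP4 itself lay between 3.71 and 4.61, below the array medians too. SRM, which makes the polyamine spermidine, was lower by the same criterion in the list of polyamine synthesis and amino acid uptake (-0.53 ± 0.13 SE), a call lost in 6 of the 8 fits, and did not pass over the list of MYC-activated genes alone. CCN1, a secreted matrix-associated protein, was lower in the lists of dedifferentiated melanoma and of YAP targets (-0.68 ± 0.16 SE), calls lost in 4 and 2 of the 8 fits. Over all genes, none passed: of 17491 genes, 0 were higher and 0 lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and the smallest adjusted p was 0.987. At an unadjusted p under 0.05 there were 665 genes, 435 of them higher and 230 lower with doxycycline, where chance alone would give about 875. The groups did not overlap for 458 genes, or 2.62% of all genes, against 2.86% expected by chance. Without vehicle replicate 1, limma still called 0 genes, with 858 at an unadjusted p under 0.05. In simulated data with the spread of these arrays and errors independent between genes, 81 of 100 genes changed by 1 log2 unit were called. Another 100 genes were changed by 2 log2 units in the same data, which eases the adjusted threshold. The share called therefore need not hold for a change in the tumour cells of a mixed node.

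MYC itself, whose probes can read both the endogenous gene and any transgene sequence they match, was at 6.05 ± 0.33 (SD, n = 4) with vehicle and 5.70 ± 0.12 (SD, n = 4) with doxycycline. The difference was -0.35 on the log2 scale, with a 95% confidence interval from -0.70 to 0.01, and it did not pass (limma adjusted p = 0.987). MAX, the obligate partner of MYC, was at 8.99 ± 0.33 (SD, n = 4) with vehicle and differed by 0.01 ± 0.18 (SE) with doxycycline. The MAX difference turned below 0 when array medians were centred (-0.000758), under cyclic loess (-0.03) and without vehicle replicate 1 (-0.03), vehicle replicate 3 (-0.02), vehicle replicate 4 (-0.08), doxycycline replicate 2 (-0.03) or doxycycline replicate 3 (-0.06). Of the 13 measured genes of the MYC network, 0 passed, 6 had a difference above 0 and 7 below 0, and the differences ranged from -0.35 for MYC to 0.18 for MNT, a MAX-binding repressor, whose difference was 0.11 without vehicle replicate 1 and 0.09 without doxycycline replicate 3. The MYC network as a list gave an adjusted p of 0.321 in limma's camera test.

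The genes with the smallest p in each direction are given as values, since none passed over all genes. Lower with doxycycline were CCN1, a secreted matricellular protein and YAP target (log2 difference -0.68 ± 0.16 SE), and CD164, a sialomucin (-0.83 ± 0.19 SE). SRM, the spermidine synthase gene and a described MYC target, was at 5.17 ± 0.08 (SD, n = 4) with vehicle and 4.64 ± 0.20 (SD, n = 4) with doxycycline. GPN3, a GTPase involved in RNA polymerase assembly (-0.59 ± 0.15 SE), COL6A1, a collagen VI chain (-0.52 ± 0.14 SE), and ACLY, the ATP citrate lyase gene (-0.90 ± 0.25 SE), completed the lower set. Higher with doxycycline were LRFN1, a synaptic adhesion protein (0.57 ± 0.13 SE), HOMEZ, a homeobox gene (0.64 ± 0.14 SE), PON1, the paraoxonase gene (0.60 ± 0.14 SE), and FSD1 (0.59 ± 0.13 SE). FABP4, a fatty acid carrier of adipocytes, was at 3.79 ± 0.08 (SD, n = 4) with vehicle and 4.37 ± 0.21 (SD, n = 4) with doxycycline. CCDC80, a secreted matrix protein, differed by 0.98 ± 0.25 (SE), and its groups overlapped, as did those of ACLY. All 12 genes had a limma adjusted p of 0.987, and all 12 kept their sign without vehicle replicate 1. LRFN1, PON1, FABP4, CD164 and GPN3 had means below the array medians in both groups.

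**Figure D1:**
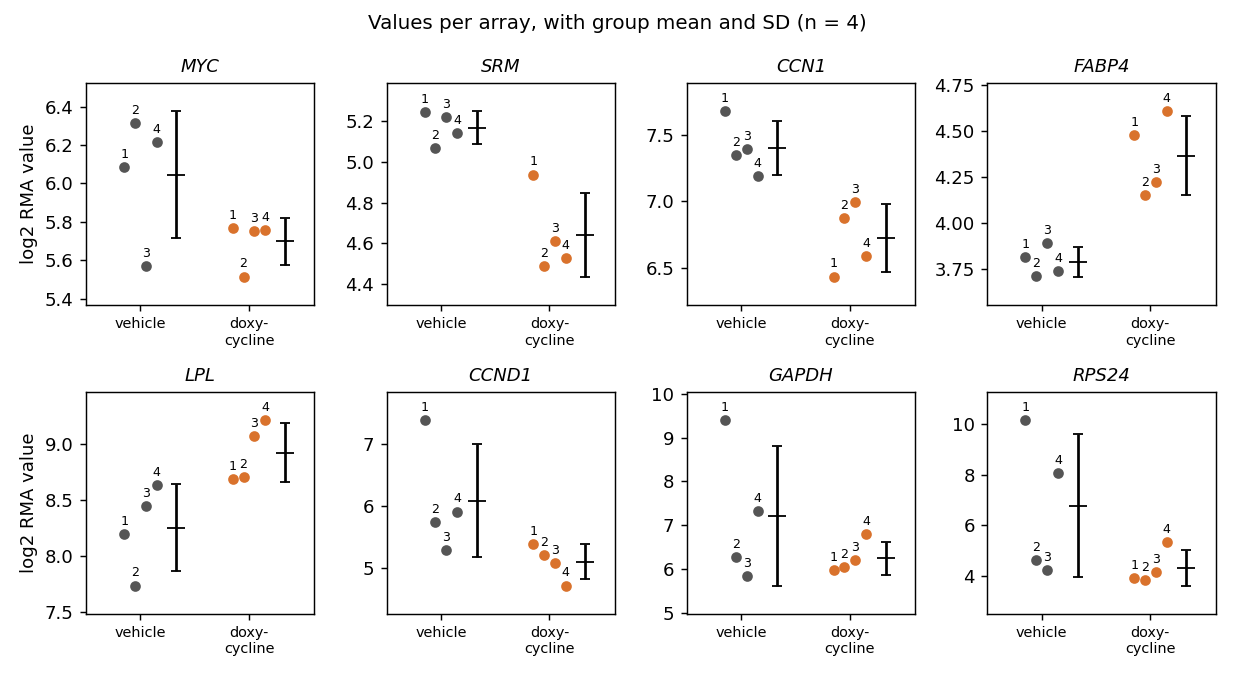
Log2 RMA values (vertical axes, a separate range per gene) of 8 genes on the 4 vehicle arrays (grey) and 4 doxycycline arrays (orange), with replicate numbers beside the points and the group mean ± SD at the right of each group. SRM, CCN1, FABP4 and LPL show groups that do not overlap, as did 2.62% of all genes, against 2.86% expected by chance. GAPDH, RPS24 and CCND1 reach their highest value in vehicle replicate 1.

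Gene lists fixed before the data were examined were then tested as groups. Of 41 lists, 15 passed limma's camera test with its preset correlation between genes of 0.01, 12 of them lower and 3 higher with doxycycline. With the correlation estimated from these arrays, 0 of the 41 lists passed, and the smallest adjusted p was 0.282 with an estimated correlation. Without vehicle replicate 1, 3 of the 15 lists passed with the preset correlation: the ribosomal proteins, the MAPK output genes and the adipocyte markers. Without that array and with an estimated correlation, 0 lists passed. Without doxycycline replicate 1, 7 lists passed. In the lists described here 0 members passed over all genes.

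Genes described as activated by MYC, which serve nucleolar function, nucleotide synthesis and proliferation, lay slightly lower with doxycycline as a list. The mean log2 difference over 51 measured members was -0.12, with 31 members below 0 and 20 above 0 (camera adjusted p = 0.00914). The adjusted p was 0.387 with an estimated correlation, and without vehicle replicate 1 the mean was -0.01 with an adjusted p of 0.890. The list also did not pass without doxycycline replicate 1 (adjusted p 0.0506), without the dimmest 50% of genes (0.0736) or with array weights (0.134). SRM was the member with the smallest p, followed by PLK1, a mitotic kinase (5.43 ± 0.28 SD with vehicle, 5.17 ± 0.15 SD with doxycycline), and LDHA, the lactate dehydrogenase A gene (4.05 ± 1.09 SD and 3.39 ± 0.17 SD). CCND2, a D-type cyclin, differed the other way, from 7.26 ± 0.17 SD to 7.54 ± 0.13 SD. Over the list alone, 0 members passed. Vehicle replicate 1 had a list mean of 0.40 above the 8-array mean, while the other 3 vehicle arrays lay between -0.12 and -0.01 and the 4 doxycycline arrays between -0.09 and -0.02. Genes of ribosome biogenesis did not pass (49 measured, mean -0.05, camera adjusted p = 0.224), nor did genes described as repressed by MYC (21 measured, mean -0.06, camera adjusted p = 0.194). Ribosome biogenesis passed when vehicle replicate 3 was left out (mean -0.09, adjusted p 0.0165). Its mean turned above 0 with array weights (0.00668) and without vehicle replicate 1 (0.06, adjusted p 0.184). In that last setting the exact two-sided permutation p of its mean was 0.0286, the smallest that 3 against 4 arrays allow, without adjustment over the lists. In the first list UTP4, a pre-rRNA processing factor, had the smallest p (4.14 ± 0.61 SD with vehicle, 3.59 ± 0.04 SD with doxycycline), and in the second CCND1, the cyclin D1 gene. The differences of LDHA, UTP4 and CCND1 went from -0.66, -0.56 and -0.99 to -0.15, -0.28 and -0.55 without vehicle replicate 1, and without vehicle replicate 3 that of PLK1 went from -0.26 to -0.40.

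With all 8 arrays, the cytosolic ribosomal protein genes had the largest mean difference of all lists, -0.59 over 37 measured members, of which 35 were below 0 (camera adjusted p = 1.53e-13). The adjusted p was 0.387 with an estimated correlation. Without vehicle replicate 1 the mean was -0.20, smaller in size than that of the adipocyte markers (0.23). In that setting the ribosomal list had a camera adjusted p of 0.00701 with the preset correlation and 0.715 with an estimated one. The exact two-sided permutation p of its mean was then 0.457. RPS25 was at 7.79 ± 1.02 (SD, n = 4) with vehicle and 6.75 ± 0.20 (SD, n = 4) with doxycycline. RPS24 went from 6.78 ± 2.84 SD to 4.32 ± 0.70 SD and RPL38 from 8.18 ± 1.49 SD to 6.84 ± 0.53 SD, while RPL9 was at 7.45 ± 0.23 SD and 7.52 ± 0.18 SD. The RPS25, RPS24 and RPL38 differences were -0.55, -1.33 and -0.67 without vehicle replicate 1, in place of -1.03, -2.46 and -1.33. The RPL9 difference turned below 0 without vehicle replicate 2 (-0.00146) and without doxycycline replicate 1 (-0.02). The list mean was 1.47, -0.27, -0.36 and 0.35 in vehicle replicates 1 to 4 and between -0.47 and -0.08 in the doxycycline arrays, so that vehicle replicates 2 and 3 lay within the doxycycline range. An exact permutation test of the list mean over the 70 assignments of the arrays gave a two-sided p of 0.229. Ribosomal protein genes have many near-identical pseudogenes, so their probe sets are uncertain as to the copy they read.

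The proliferation lists were lower in the camera test with the preset correlation. Among 59 genes of G2 phase and mitosis, 45 were below 0 and the mean was -0.20 (adjusted p = 2.78e-06, and adjusted p = 0.387 with an estimated correlation). Among 30 replication-dependent histone genes, 25 were below 0 and the mean was -0.27 (adjusted p = 1.55e-06, and adjusted p = 0.387 with an estimated correlation). Among 57 genes of S phase and DNA replication, 34 were below 0 and the mean was -0.06 (adjusted p = 0.0254, and adjusted p = 0.432 with an estimated correlation). Examples were CDCA2, a chromatin-bound phosphatase subunit (4.35 ± 0.19 SD with vehicle, 3.97 ± 0.11 SD with doxycycline), TUBB4B, a beta-tubulin (5.83 ± 1.05 SD and 4.86 ± 0.16 SD), CCNB2, a mitotic cyclin (4.42 ± 0.47 SD and 3.91 ± 0.22 SD), and TK1, the thymidine kinase gene (5.86 ± 0.22 SD and 5.45 ± 0.10 SD). The histone genes H2BC14 and H2AC13 differed by -0.98 ± 0.37 (SE) and -0.33 ± 0.13 (SE), and the mitotic kinase gene AURKA by 0.20 ± 0.13 (SE). Over each list alone, 0 members passed. Without vehicle replicate 1 the means of the mitosis and histone lists were -0.02 and -0.08, the S phase list turned to a mean of 0.00794, and the adjusted p was 0.637, 0.0867 and 0.913 for the 3 lists. The S phase list also did not pass without doxycycline replicate 1 (adjusted p 0.104) or with array weights (0.514). The differences of TUBB4B and H2BC14 were -0.46 and -0.49 without vehicle replicate 1, in place of -0.98 for both. The mean of the mitosis list was 0.64 in vehicle replicate 1 and between -0.13 and -0.05 in the other 7 arrays.

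The glycolysis, respiratory chain, mitochondrial ribosome and heat shock lists were also lower under the preset correlation. The glycolysis list had a mean of -0.28 over 19 members (camera adjusted p = 0.00532, and adjusted p = 0.387 with an estimated correlation). Its members included PKM, the pyruvate kinase gene, at 7.21 ± 0.69 SD with vehicle and 6.36 ± 0.26 SD with doxycycline, and LDHB at 6.18 ± 1.76 SD and 4.49 ± 0.43 SD. PFKL, a phosphofructokinase, differed by 0.45 ± 0.19 (SE). The nuclear-encoded respiratory chain genes had a mean of -0.15 over 40 members (adjusted p = 0.000283, and adjusted p = 0.387 with an estimated correlation), with SDHC, a succinate dehydrogenase subunit, at -0.49 ± 0.18 (SE). Doxycycline inhibits mitochondrial translation as well as inducing the transgene. The mitochondrial ribosome list had a mean of -0.09 over 45 members, 31 of them below 0 (adjusted p = 0.00532, and adjusted p = 0.387 with an estimated correlation), with MRPS22 at -0.55 ± 0.21 (SE) and MRPS10 at 0.38 ± 0.19 (SE). The heat shock list had a mean of -0.20 over 11 members (adjusted p = 0.0241, and adjusted p = 0.387 with an estimated correlation), with HSPH1, a chaperone, at -0.49 ± 0.30 (SE). Without vehicle replicate 1 none of the 4 passed, with a mean of -0.10 for glycolysis (adjusted p 0.218), -0.03 for the respiratory chain (0.525), -0.02 for the mitochondrial ribosome (0.563) and -0.02 for heat shock (0.822). Without doxycycline replicate 1, glycolysis (adjusted p 0.0706), the mitochondrial ribosome (0.0506) and heat shock (0.0747) did not pass. Heat shock was also lost without doxycycline replicate 2 (0.110) or 3 (0.0501) and with array weights (0.0800). Without the dimmest 50% of genes the mitochondrial ribosome list had a mean of 0.02 and an adjusted p of 0.783. The differences of PKM, LDHB, MRPS22 and HSPH1 were -0.51, -0.84, -0.32 and -0.11 without vehicle replicate 1, and that of MRPS10 was 0.23 without doxycycline replicate 3. Genes of the integrated stress response did not pass (33 measured, mean -0.04, camera adjusted p = 0.116), though it did without vehicle replicate 2 (mean -0.06, adjusted p 0.0355), and leaving out vehicle replicate 1 gave an adjusted p of 0.402. ATF4, the transcription factor of that response, was at 5.97 ± 0.34 SD with vehicle and 5.58 ± 0.15 SD with doxycycline, a difference of -0.39 that was -0.23 without vehicle replicate 1.

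Genes that report ERK signalling in melanoma had a mean of -0.20 over 18 measured members, 13 of them below 0 (camera adjusted p = 0.00131). The adjusted p was 0.282 with an estimated correlation. Without vehicle replicate 1 the mean was -0.15, with a camera adjusted p of 0.0372 with the preset correlation and 0.690 with an estimated one. CCND1 was at 6.08 ± 0.91 (SD, n = 4) with vehicle and 5.09 ± 0.28 (SD, n = 4) with doxycycline. PHLDA1 was at 7.35 ± 0.44 SD and 6.86 ± 0.16 SD, and DUSP5, an ERK phosphatase, at 6.02 ± 0.46 SD and 5.59 ± 0.24 SD, while EPHA4, an ephrin receptor, differed by 0.26 ± 0.15 (SE). The list mean was 0.10 ± 0.14 (SD, n = 4) with vehicle and -0.10 ± 0.03 (SD, n = 4) with doxycycline, and the exact two-sided permutation p was 0.0571, where 0.0286 is the smallest this design allows. Immediate early genes, which tissue handling can also induce, had a mean of -0.15 over 19 members (camera adjusted p = 0.0250). That adjusted p was 0.387 with an estimated correlation, and without vehicle replicate 1 the mean was -0.12 with an adjusted p of 0.0867. The call was also lost without vehicle replicate 3 (adjusted p 0.0841), doxycycline replicate 1 (0.218) or doxycycline replicate 2 (0.0636), and with ranks in camera (0.0541). EGR1, a member of both lists, was at 6.75 ± 0.46 SD with vehicle and 6.35 ± 0.18 SD with doxycycline. JUN, an AP-1 subunit, differed by -0.33 ± 0.18 (SE). When vehicle replicate 1 was left out the differences of CCND1, PHLDA1 and JUN were -0.55, -0.28 and -0.14, and without vehicle replicate 2 those of DUSP5 and EGR1 were -0.26 and -0.24.

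Genes of the dedifferentiated, invasive melanoma state had a mean of -0.14 over 25 measured members (camera adjusted p = 0.0250). The adjusted p was 0.402 with an estimated correlation, and without vehicle replicate 1 the mean turned to 0.00165 with an adjusted p of 0.890. The call was also lost without doxycycline replicate 1 (adjusted p 0.159) or 4 (0.0704), without the dimmest 25% of genes (0.0544) and with array weights (0.190). CCN1 was lower when adjusted over the list alone (limma adjusted p = 0.0236), and likewise among the 19 measured YAP targets (limma adjusted p = 0.0179), a list that did not pass in camera (mean -0.08, adjusted p = 0.274, and mean -0.05 without vehicle replicate 1). Leaving out one array at a time moved the first value between 0.0163 and 0.106, with the call lost without vehicle replicate 2, vehicle replicate 3, doxycycline replicate 1 or doxycycline replicate 4, and the second between 0.0124 and 0.0802, lost without doxycycline replicate 1 or 4. NT5E was at 6.36 ± 1.93 SD with vehicle and 5.17 ± 0.80 SD with doxycycline, a difference of -1.19 that was -0.26 without vehicle replicate 1, and RXRG, a nuclear receptor of neural crest-like cells, differed by 0.37 ± 0.13 (SE). Pigmentation and MITF target genes did not pass (26 measured, mean 0.04, camera adjusted p = 0.773, and mean 0.00206 without vehicle replicate 1), and TRPM1, a melanocyte channel gene, had the smallest p among its members that were higher (5.07 ± 0.13 SD and 5.34 ± 0.23 SD), a difference of 0.27 that was 0.16 without doxycycline replicate 3. Matrix and mesenchymal genes did not pass either (40 measured, mean -0.09, adjusted p = 0.215), with COL6A1 at the smallest p and SPARC, a matricellular protein, at 0.33 ± 0.15 (SE) the other way, and they passed without vehicle replicate 2 (mean -0.14, adjusted p 0.0439) or 3 (mean -0.14, adjusted p 0.0447). Their mean turned to 0.03 without vehicle replicate 1 (adjusted p 0.670). Among genes of polyamine synthesis and amino acid uptake, SRM was lower when adjusted over the list alone (limma adjusted p = 0.0267), a call lost when any one of 6 arrays was left out (highest adjusted p 0.115, without doxycycline replicate 2), and the list itself did not pass (16 measured, mean -0.07, adjusted p = 0.371). The mean of that list turned above 0 without vehicle replicate 1 (0.06, adjusted p 0.617) and without the dimmest 50% of genes (0.03, adjusted p 0.961).

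Markers of host cells that a homogenized node can hold were compared in the same way, as signal on human probes. The adipocyte markers were higher with doxycycline, with a mean of 0.29 and 12 of 13 measured members above 0 (camera adjusted p = 3.58e-05). The adjusted p was 0.387 with an estimated correlation. Without vehicle replicate 1 the mean was 0.23, with a camera adjusted p of 0.00377 with the preset correlation and 0.690 with an estimated one. The exact two-sided permutation p of the list mean was then 0.200. FABP4, CIDEC, a lipid droplet protein, and LPL, the lipoprotein lipase gene, were higher when adjusted over the list alone (limma adjusted p = 0.0121, 0.0222 and 0.0222). The FABP4 call held with each array left out, though its values lay below the median of every array. The CIDEC call was lost without doxycycline replicate 3 or 4 (highest adjusted p 0.0756), and the LPL call was lost without vehicle replicate 2 or doxycycline replicate 3 or 4 (highest adjusted p 0.0756). CIDEC was at 4.85 ± 0.39 (SD, n = 4) with vehicle and 5.47 ± 0.14 (SD, n = 4) with doxycycline, and LPL at 8.25 ± 0.39 SD and 8.92 ± 0.26 SD, whereas PLIN1, a lipid droplet coat protein, differed by -0.13 ± 0.16 (SE), and by -0.25 without vehicle replicate 1 and -0.02 without vehicle replicate 4.

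Fibroblast and stromal markers had a mean of 0.18, with 15 of 19 members above 0 (camera adjusted p = 0.00156), and included CXCL13, a B cell-attracting chemokine (0.53 ± 0.16 SE), DES, the muscle intermediate filament desmin (0.61 ± 0.19 SE), and LUM, a matrix proteoglycan (-0.12 ± 0.16 SE). Their adjusted p was 0.387 with an estimated correlation, and without vehicle replicate 1 the mean was 0.14 with an adjusted p of 0.0556. The list of skeletal muscle and epithelial markers had a mean of 0.24 over 16 members, 11 of them above 0 and 5 below 0 (camera adjusted p = 0.00952), with adjusted p = 0.387 with an estimated correlation. It did not pass without vehicle replicate 1 (mean 0.18, adjusted p 0.0867) or without doxycycline replicate 1 (mean 0.16, adjusted p 0.180). In an exact permutation test its mean gave a two-sided p of 0.200. The members with the smallest p were MB, the myoglobin gene (0.44 ± 0.18 SE), KRT10, a keratin (0.30 ± 0.13 SE), and TNNT3, a fast muscle troponin (1.01 ± 0.46 SE), while KRT14, another keratin, differed by -0.25 ± 0.15 (SE). The MB difference was 0.29 without vehicle replicate 1, that of KRT14 was -0.13 without vehicle replicate 2, that of TNNT3 was 1.52 without doxycycline replicate 4, and that of LUM was -0.01 without doxycycline replicate 3. B cell, T and NK cell, myeloid, pan-leukocyte, endothelial and erythroid markers did not pass, with camera adjusted p of 0.959, 0.456, 0.189, 0.575, 0.120 and 0.116. Endothelial markers had a mean of 0.10 and passed without vehicle replicate 2 (mean 0.14, adjusted p 0.0356), while without vehicle replicate 1 the mean was 0.06 (adjusted p 0.402). In that setting the B cell and T and NK cell means turned from 0.01 and 0.05 to -0.04 and -0.01. In exact permutation tests of the 9 marker list means the smallest two-sided p was 0.0286, for fibroblast and stromal markers, which is the smallest the design allows, and 0.257 after Benjamini-Hochberg adjustment over the 9 lists; without vehicle replicate 1 the exact p of that list was 0.0571. That list was lower in all 4 vehicle arrays (-0.09 ± 0.11 SD, n = 4) than in all 4 doxycycline arrays (0.09 ± 0.06 SD, n = 4). The margin was narrow, with 0.0174 in vehicle replicate 3 and 0.0295 in doxycycline replicate 4. With only members above the median level, the smallest adjusted exact permutation p over the marker lists was 0.514, against 0.257 with all members.

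**Figure D2:**
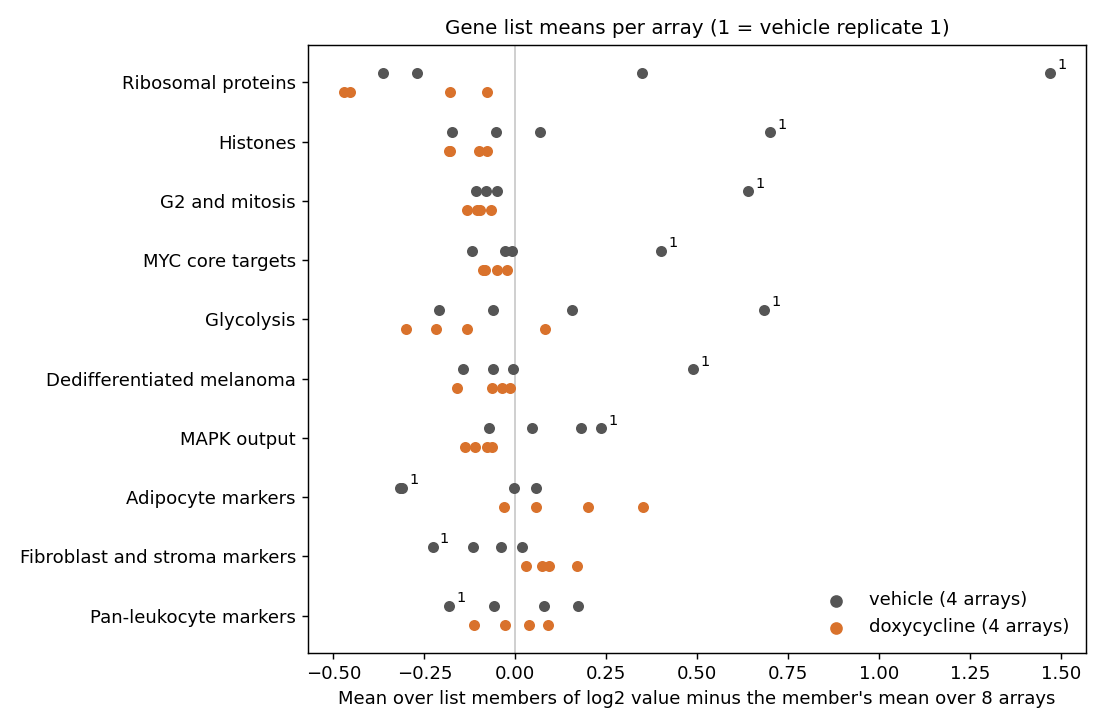
Mean over the measured members of 10 gene lists (rows) of the log2 value minus each member's mean over the 8 arrays (horizontal axis), with a point for each of the 4 vehicle arrays (grey) and 4 doxycycline arrays (orange); the point marked 1 is vehicle replicate 1. For ribosomal proteins that array lies at 1.47 and for G2 and mitosis at 0.64, to the right of the other 7 arrays.

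Other lists tested did not pass in camera. They were antigen presentation (adjusted p = 0.0760), nucleotide synthesis (0.116), the unfolded protein response (0.123), hypoxia (0.189), TGF-beta targets (0.274), chemokines and cytokines (0.411), apoptosis (0.530), p53 targets (0.700), autophagy and lysosome (0.767), cholesterol synthesis (0.773), lymphatic spread (0.782) and type I interferon-stimulated genes (0.872). Of these, 4 passed, all lower, when single vehicle arrays other than replicate 1 were left out, and none of the 4 passed without replicate 1. Antigen presentation had a mean of -0.12 and passed without vehicle replicate 2 (mean -0.15, adjusted p 0.0250), 3 (mean -0.16, adjusted p 0.0240) or 4 (mean -0.14, adjusted p 0.0401). Nucleotide synthesis and the unfolded protein response passed without vehicle replicate 2 (adjusted p 0.0250 and 0.0260) or 3 (0.0148 and 0.0468), and hypoxia passed without vehicle replicate 2 (0.0340). Leaving out vehicle replicate 1 gave a mean of -0.02 for antigen presentation (adjusted p 0.890) and -0.000946 for hypoxia (0.890). In the same setting the mean turned from -0.11 to 0.02 for nucleotide synthesis (adjusted p 0.890), from -0.13 to 0.03 for the unfolded protein response (0.673) and from -0.01 to 0.01 for cholesterol synthesis (0.890). Nucleotide synthesis also turned to 0.06 without the dimmest 50% of genes (0.623). The median, the mean and the camera direction differed in sign for the chemokine (median 0.03, mean -0.04), polyamine, p53, autophagy, interferon and B cell lists, and for none of the 15 lists that passed. The comparison covers doxycycline and Omomyc together, since a group given doxycycline without the transgene was not analysed here.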

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

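All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. Of 224 groups of 4 arrays examined, 18 had 1 array far from the other 3, and 11 of the 18 were in vehicle replicate 1. Chance would give about 11.2 if the groups were independent, which overlapping lists and their members are not. Besides MYC and MAX, the genes came from those with the smallest p and from lists that passed, so the counts are descriptive only.

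Vehicle replicate 1 stood apart from the other 7 arrays, with a mean correlation of 0.941 against 0.971 on average for the other 3 vehicle arrays. Proteasome, chaperonin and translation factor genes, used by tumour and host cells alike, had a median excess of 0.501 log2 units in it (51 genes, 44 above 0). This was higher than 100% of 10000 random lists matched on level, whose central range was -0.21 to -0.04. A shift that depends only on brightness would keep the median within that range, so the tables argue against it as the whole cause. A candidate explanation is more human tumour RNA in that node, which stays open. The common genes go with it, but they do not separate human from mouse RNA, since reading of mouse transcripts was not measured. Of 5 host marker lists only T and NK cell (-0.26) and adipocyte markers (-0.36) had a mean excess below the central range of matched random lists. Pan-leukocyte (-0.21), B cell (-0.20) and endothelial markers (-0.18) lay within it at percentiles of 6.96, 3.39 and 4.55. Melanocyte genes were low in that array (list mean -0.15, and MLANA at 4.60 against 5.63 to 6.21 in the other 7). Dedifferentiated melanoma genes were high in it (list mean 0.49 against -0.16 to -0.01 in the other 7). Which state SkMel147 cells hold was not tested, so neither list decides. A treatment effect that set all 4 vehicle arrays above all 4 doxycycline arrays was not seen in the common genes. In their mean, vehicle replicates 2 to 4 lay at -0.21 to -0.02 and the doxycycline arrays at -0.20 to 0.06. A smaller shared effect cannot be excluded with so few arrays. Vehicle replicate 1 lay 0.705 above the highest other vehicle array, where the other 7 arrays spanned 0.271. That array was picked because it stood apart, so this gap tests nothing. A treatment effect in only some nodes cannot be tested with 1 such array and stays open.

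The 100 genes with the highest excess in vehicle replicate 1 also varied among the other 7 arrays. Their median deviation lay above the matched lists in 2 arrays, 1 of each group: vehicle replicate 4 (0.29) and doxycycline replicate 4 (0.14). Human tumour RNA in differing amounts in several nodes may account for this, and no biological explanation was tested.

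Adipocyte markers were higher with doxycycline by 0.29. If less human RNA had raised all host markers alike, the adipocyte and pan-leukocyte lists would have moved together, and their group differences lay 0.29 apart (exact two-sided permutation p of 0.171), with -0.01 for pan-leukocyte, 0.01 for B cell and 0.05 for T and NK cell markers. These 3 values lay near 0, where that explanation predicts a rise. Muscle and epithelial (0.24), fibroblast (0.18), erythroid (0.12), endothelial (0.10) and myeloid markers (0.08) lay above 0 as it predicts. Single arrays moved these values: myeloid was 0.03 without vehicle replicate 1, and pan-leukocyte was -0.07 without vehicle replicate 1 and 0.05 without vehicle replicate 2. No difference from the adipocyte list reached the threshold, with exact two-sided permutation p from 0.0857 for B cell to 0.857 for muscle and epithelial markers, so that explanation stays open. More fat tissue in the excised samples may also account for it, with an exact two-sided permutation p of 0.114 for the list mean, and an effect of the treatment stays open and untested.

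Other splits of the 8 arrays into 4 and 4 were fitted in the same way. The real split called 0 genes, a count that all 35 splits reach by necessity, so that this count tests nothing, and the highest other count was 4. Of the 35 splits, 24 gave at least the real 665 genes at an unadjusted p under 0.05 in limma, with 1306 as the highest. For gene lists, 4 of 35 splits, the real one included, called at least 15 lists, with 16 as the highest other count, so chance could not be excluded for the number of lists.

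Other values far from the 3 remaining arrays of their group are given without explanation. In vehicle replicate 1 the list means were 0.36 for antigen presentation, 0.64 for G2 and mitosis, 0.41 for polyamine synthesis and amino acid uptake, 0.35 for ribosome biogenesis and 0.57 for the unfolded protein response, against -0.04, -0.08, -0.09, -0.08 and -0.10 in the other 3 vehicle arrays. The same array had H2BC8 at 7.96, PKM at 8.23, IER3 at 7.17, GMNN at 4.09 and CIDEC at 4.26, against means of 5.92, 6.86, 6.41, 3.09 and 5.04. In doxycycline replicate 4 the interferon list was at 0.19 and the respiratory chain list at 0.0578, against -0.06 and -0.12. Vehicle replicate 2 had the TGF-beta list at 0.0702 and KRT14 at 5.75, against -0.00245 and 5.29. MYC was at 5.52 in doxycycline replicate 2 against 5.76, HOMEZ at 4.93 in doxycycline replicate 3 against 5.44, and CHAF1A at 3.91 in doxycycline replicate 3 against 4.32.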

How the results depend on the processing

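The count of 0 genes stayed at 0 in all 21 other settings chosen before the data were examined, in limma, with 528 to 998 genes at an unadjusted p under 0.05 when 1 array was left out. With the first residual component as a covariate, added after seeing the data, 50 genes were called, all lower; this covariate leaves the differences as they are and removes residual variance by construction. The planned surrogate variable was not run. The 15 lists became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.343), and ranged from 3 (without vehicle replicate 1) to 22 with 1 array left out, with 7 without doxycycline replicate 1. In alternatives added after seeing the data they became 0 without vehicle replicate 1 with an estimated correlation, 0 with the replicate block and an estimated correlation, 9 with the level of common human genes as a covariate and 18 (3 higher, 15 lower) with the first residual component. Without vehicle replicate 1 the dedifferentiated melanoma list turned to 0.00165 and the S phase list to 0.00794, with either correlation, and with other single arrays left out they reached -0.21 (vehicle replicate 3) and -0.11 (vehicle replicate 4); the cause of the list changes was not tested. Among named genes, 0 of 166 were called in any setting chosen before the data were examined, and 4 changed sign in at least 1 (KLF1, MAX, RPL9 and TGFB1). The deviations of same-numbered arrays correlated at -0.0487, 0.148, 0.0858 and 0.00293. Differently numbered arrays were not compared, so whether the numbers pair the arrays stays open. With the replicate block 0 genes (734 at an unadjusted p under 0.05 in limma) and 16 lists were called, with antigen presentation added (camera adjusted p 0.0412). Signal over background was not assessed here.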

Other observations

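Values of 5 skeletal muscle genes are given per array, with no test of whether they vary together. TNNT3, a troponin of fast fibres, was at 6.36, 6.72, 6.52 and 7.97 in vehicle replicates 1 to 4 and at 8.54, 8.59, 8.12 and 6.37 in doxycycline replicates 1 to 4. MYL11, a fast myosin light chain, was at 5.57, 6.05, 5.73 and 6.84 with vehicle and at 7.42, 7.27, 6.80 and 5.95 with doxycycline. CKM, the muscle creatine kinase gene, was at 4.79, 4.78, 5.23 and 6.07 with vehicle and at 6.27, 6.04, 6.18 and 4.82 with doxycycline. PVALB, a calcium-binding protein, was at 4.82, 5.54, 5.57 and 6.28 with vehicle and at 6.48, 6.06, 5.94 and 5.48 with doxycycline. MYH2, a myosin heavy chain, was at 5.12, 5.49, 5.71 and 5.65 with vehicle and at 6.05, 5.95, 5.80 and 5.45 with doxycycline. These genes were chosen after their values were seen, and 0 of them passed (limma adjusted p = 0.987).

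Among lists that did not pass, single members differed by more than their list. GABARAPL1, an autophagy gene, was at 7.71 ± 0.27 (SD, n = 4) with vehicle and 8.51 ± 0.63 (SD, n = 4) with doxycycline, and CXCL8, a neutrophil-attracting chemokine, at 5.62 ± 1.10 (SD, n = 4) and 4.60 ± 0.15 (SD, n = 4), a difference of -1.02 that was -0.62 without vehicle replicate 1. TEK, an endothelial receptor, differed by 0.50 ± 0.16 (SE), and CXCR4, a chemokine receptor, by -0.35 ± 0.15 (SE). The limma adjusted p of each was 0.987.

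Vehicle replicate 1 also had high values of ERRFI1, an EGFR inhibitor, at 8.96 against a mean of 4.70 in the other 7 arrays, of IFI16, a DNA sensor, at 7.44 against 3.69, and of ANXA1, an annexin, at 9.04 against 5.34. MLANA, a melanocyte antigen, was at 4.60 in this array and between 5.63 and 6.21 in the other 7. These genes were chosen after their values were seen.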
